A study of Mus musculus with 4 samples.

How the data were processed

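ATAC-seq libraries were made from 4 sorted T helper populations of house dust mite treated mice at day 15, with 3 biological replicates of 1000 cells each, 30 minutes of tagmentation, 16 PCR cycles and paired reads of 125 bases, per the labels' protocols. The labels disagree on the day: the titles say 15 for all 4 populations, while the descriptions of other effector and naive cells carry D10, and the titles and protocol were followed. The source label of naive cells names lung and airways where the protocol names the mediastinal lymph node, and the protocol was followed. Differential regions came from DiffBind on build mm9, per the submitters' processing notes, which give no version. The aligner, peak caller, read shift, normalization, threshold, any filter by direction and number of libraries in each contrast are not given in the sources used here.

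The 6 deposited tables hold chromosome, start, end and a fold that was read as log2, the scale on which the authors' tool reports it, per the submitters' processing notes. At the 4 regions listed in all 3 tables of a triple of populations the folds added up exactly (largest residual 0), so each fold was taken as first-named minus second-named population. Additive folds leave the overall sign open, and for naive versus other effector cells 0 regions linked the tables. The sign was read from the fixed naive gene list, whose regions were higher in naive cells at 291 against 0 for other effector, 125 against 7 for Th2 and 65 against 5 for Treg cells, so the direction of that list is no independent evidence. The tables hold no FDR, p-value, count or replicate.

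The build named in the labels conflicts with the tables. All 11 unplaced sequences they name carry accessions of GRCm38 type, and 21.4% of distinct regions lay within 1 kb of a gene end of the GRCm38.p6 gene table, against 4.25% to 6.15% after shifting them by 10 to 1000 kb. Over 201 shifts for each of 21 chromosomes, 0 was best on 20. Coordinates are therefore given as GRCm38, as in the tables and 1-based. The gene table (21887 protein-coding genes) gives gene starts and ends but no strand, exons or UTRs, so the planned share near start sites became the share of region midpoints within 1 kb of either gene end, and regions are described only as inside or outside a gene. Each region was assigned to the gene holding its midpoint, otherwise to the gene with the nearest end within 100 kb. Gene-end counts of housekeeping genes and of genes used by all T cells did not use this assignment. They took any midpoint within 1 kb of an end of the gene, even where the region was assigned to a neighbouring gene.

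Regions of the 6 tables were merged where they overlapped by at least 1 bp, giving 52537 regions used as background. Every background region is listed at least once, so a gene list rich in 1 direction tends to be poor in others. Calls below the rest are therefore no separate evidence. Gene lists were tested with a two-sided Fisher exact test over merged regions and Benjamini-Hochberg adjustment. The planned 72 tests of 12 lists in 6 comparisons, both directions together, gave 15 lists above and 12 below the rest of the regions. The text gives the 108 tests by direction, which were added after the data were examined. Regions of a gene are not independent, so gene counts stand beside them. With genes as units, a gene counted as listed when any of its regions was. That raises the odds ratio of lists with many regions per gene, in either direction. A pass or turn seen only with genes as units therefore settles no direction. All 177 list genes matched the table. Pparg is on both the Th2 and lipid lists, and Il10 on both the Th2 and Treg lists. Windows of 100 kb were compared with a Poisson mean over windows with a merged region and, added after the data were examined, with a hypergeometric tail given the merged regions of each window, and chromosome shares with Fisher's exact test. Overlaps between directions were also counted with bedtools 2.31.1. Intervals are exact 95% binomial intervals. Tested on simulated data with 20 lists on the 52537 regions, 90% of gene lists planted at 2.5 times the base rate were recovered and 2.36% of others called. Regions were drawn independently with adjustment over 12 lists, so these rates may not hold for real regions, which are not independent within a gene. For the Poisson test, 100% of 400 planted windows were recovered with 0.0883% of others called. All regions of a planted window were set as listed, so this recovery was fixed in advance. The hypergeometric test was not simulated.

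Gene lists, named genes and tests were fixed before the data were examined, except where said. Named are Il4, Il5, Il13, Rad50, Gata3, Il1rl1, Pparg, Ccr8, Foxp3, Il2ra, Ctla4, Ikzf2, Ccr7, Tcf7, Lef1, Ifng, Tbx21 and Cxcr3 always, per comparison and per direction the 5 genes with most regions, per population the 5 with most distinguishing regions, and per comparison the 3 regions with the largest absolute fold. Some genes that the rule takes are not reported. Ties went to the larger fold and then the symbol. Other members of a list are examples chosen after their counts were seen. Cd44, Il2ra, Il1rl1 and Tnfsf8 belong to sort markers and are no finding between populations. Their regions stayed in the tests of the Th2, Treg and activation lists, and no test without them is given. Part of those odds ratios may therefore come from the sort. Lists of other cell types covered B cells, myeloid cells, granulocytes and mast cells, epithelium, and CD8 and natural killer cells. No granulocyte and mast or epithelial list passed in any direction, the highest counts being 7 regions each.

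A region absent from a table need not be equally accessible: 9079 merged regions stood only in other effector versus Th2. Alternatives were a subset of the regions by fold, other overlaps, distances, windows and units, and, added after the data were examined, single directions, nearest gene ends, exclusion of unplaced sequences and the mitochondrial-like segment, the 3 tables without other effector cells, and windows given their merged regions. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.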

Results

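Chromatin accessibility was measured by ATAC-seq, which marks open DNA by transposase insertion, in T helper cells of mice sensitized to and challenged with house dust mite, an allergen used to model asthma. At day 15, 4 populations were sorted: Th2 cells (CD44+ ST2+ CD30L+), other effector cells (the non-Th2 memory cells, CD44+ ST2- CD30L+), regulatory T cells (Treg, CD25hi CD30L-) and naive cells (CD44lo). The first 3 came from lung with airways and the naive cells from the mediastinal lymph node, so every contrast with naive cells is also a contrast of tissues. Each population had 3 biological replicates of 1000 cells per the labels' protocols, and the data analysed here were 6 lists of differentially accessible regions, 1 for each pair of populations. Those lists hold a position and a log2 fold for each region, which is the authors' own value throughout. Replicate values, p-values and read counts are not given in the sources used here, so depth is unknown and no fold has an error of its own. Intervals and tests below are over regions, which are not replicates, and cover counting error only.

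The 6 lists held between 5300 and 28175 regions. Naive and Th2 cells differed at 9916 regions, 4837 higher in naive and 5079 higher in Th2 cells. Naive and Treg cells differed at 6516 regions, 3025 higher in naive and 3491 higher in Treg cells. Treg and Th2 cells gave the shortest list, 5300 regions, of which 1759 were higher in Treg and 3541 in Th2 cells. Other effector cells stood apart: 17700 regions separated them from naive cells, 28175 from Th2 cells and 24765 from Treg cells, and all of these were lower in other effector cells. Whether the lists were filtered by direction before deposit is not given in the sources used here. Merging regions that overlapped gave 52537 regions, 49848 of them assigned to a protein-coding gene.

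**Figure D1:**
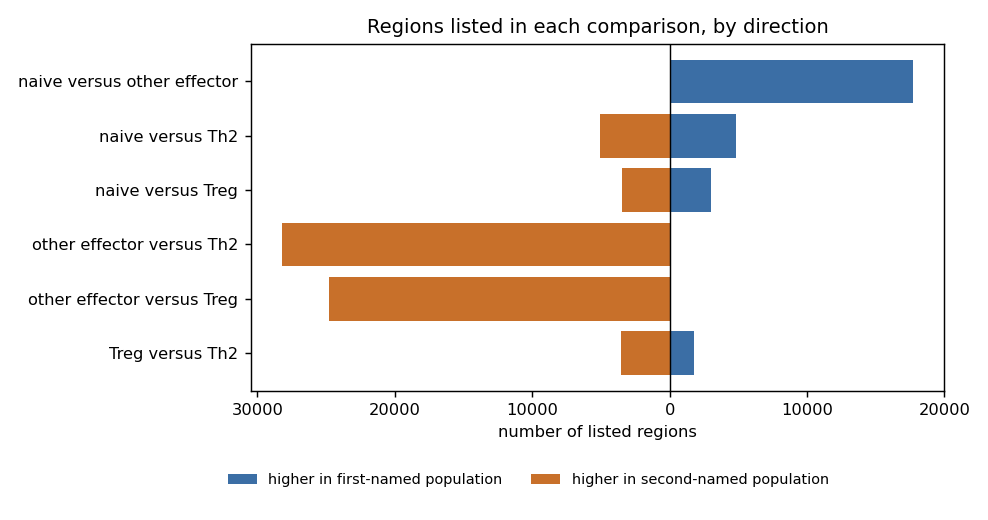
Number of listed regions in each of the 6 comparisons (horizontal axis, counts to both sides of 0), split by the population in which the region was more accessible. The 3 comparisons with other effector cells have bars on 1 side only, whereas naive versus Th2 cells splits into 4837 and 5079 regions.

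Naive versus Th2 cells asked which chromatin distinguishes allergen-responding Th2 cells from resting T helper cells. Genes of type 2 immunity were more accessible in Th2 cells. Il13 and Il5, cytokine genes of allergic inflammation, had 5 and 2 regions higher in Th2 cells, Il4 had 1, and Rad50, the gene between Il5 and Il13 that holds their locus control region, had 2. Pparg, a nuclear receptor of lipid metabolism, had 8, and Il1rl1, which encodes the sort marker ST2 and is therefore no finding, had 11. None of these genes had a region higher in naive cells. Of the 31 genes on the Th2 list, 25 had a region higher in Th2 cells, with 94 of the list's 218 regions against 9.53% of other regions (odds ratio 7.20, Fisher adjusted p = 1.42e-36). The 94 include the 11 of Il1rl1.

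Within this list Rbpj, the DNA-binding partner of Notch, had 11 regions, Il10 7, Igfbp7 and Bhlhe40 6 each, and Il6, Plac8 and Tnfsf11 5 each. Gata3 and Ccr8 had none higher in Th2 than in naive cells. The largest folds in the authors' deposited table were 7.16 for Il13, 7.11 for Il4, 6.56 for Il5, 6.77 for Rad50 and 7.24 for Pparg. The Il4 region lay inside the gene on chromosome 11 at 53617207 to 53617866, and that of Il13 at 53626744 to 53627138, outside the gene and 4383 bp from its nearer end. The strongest Pparg region lay inside the gene on chromosome 6 at 115440207 to 115441072. The lipid list had 21 of 122 regions higher in Th2 cells, over 10 of 20 genes (odds ratio 1.95, Fisher adjusted p = 0.0253), among them 8 regions of Pparg and 4 of Plin2, the lipid droplet coat protein. Pparg is also on the Th2 list, so the lipid result is not separate from that of the Th2 list. The activation and tissue list had 39 of 234 (odds ratio 1.88, Fisher adjusted p = 0.0029), led by Cd44 with 8, a sort marker, and Runx2 with 6. Neither list passed with regions assigned only within 10 kb (Fisher adjusted p = 0.0520 and 0.587) or without the tables of other effector cells (Fisher adjusted p = 0.0738 for each). The genes with most regions higher in Th2 cells were Atxn1 (12), Itpr1, Rbpj, Myo1e and Il1rl1 (11 each). Myeloid genes had 8 of 50 regions higher in Th2 cells (odds ratio 1.78, Fisher adjusted p = 0.285), which with genes as units passed (Fisher adjusted p = 0.0486). The Treg list had 30 of 208 and the Th1 and Th17 list 21 of 142 (Fisher adjusted p = 0.0653 and 0.105), and with genes as units both passed (Fisher adjusted p = 0.00408 and 0.00181). Genes as units favour lists with many regions per gene in either direction, so these passes settle no direction. Without the tables of other effector cells the myeloid, Treg and Th1 and Th17 lists did not pass (Fisher adjusted p = 0.693, 1 and 0.877). Regions of the naive list were scarce among those higher in Th2 than in naive cells, with 7 of 385 (odds ratio 0.172, Fisher adjusted p = 6.08e-09), a call that ended and turned with genes as units (odds ratio 1.14, Fisher adjusted p = 0.978). Of the 385, 291 were higher in naive than in other effector cells, a list sharing 0 regions with this direction. The scarcity is therefore no separate evidence.

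**Figure D2:**
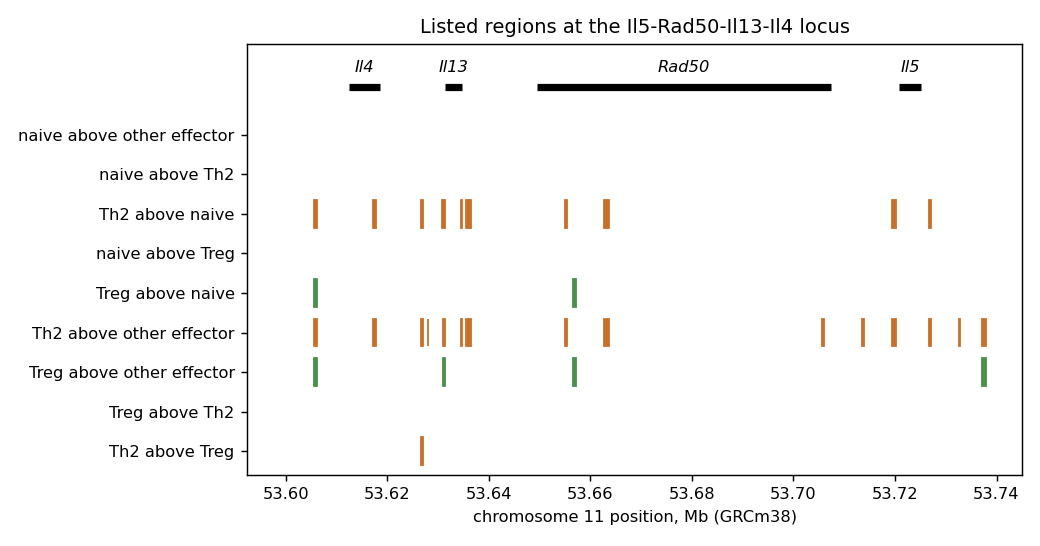
Listed regions at the Il4, Il13, Rad50 and Il5 genes on chromosome 11 (horizontal axis, position in Mb, GRCm38), with 1 line for each comparison and direction and black bars for the genes. Between 53592460 and 53745103, 11 regions were higher in Th2 than in naive cells, 2 higher in Treg than in naive cells and 1 higher in Th2 than in Treg cells, and 0 were higher in naive cells.

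In the other direction, 125 of the 385 regions of the naive list were higher in naive than in Th2 cells, over 14 of 17 genes (odds ratio 4.84, Fisher adjusted p = 7.94e-36). The sign of the folds was read from this list, so its direction in each comparison with naive cells is no independent evidence. Lef1 and Tcf7, transcription factors of naive T cells, had 19 and 6 regions, and Ccr7, the lymph node homing receptor, had 7. Foxp1 had 25, Tgfbr3 24, Satb1 19 and Bach2 18, which with Lef1 were the genes with most regions in this direction and, with 28, 25, 19 and 19 regions for Foxp1, Tgfbr3, Satb1 and Bach2, in both directions together. The largest fold next to Tcf7 in the authors' deposited table was 9.95, at 52313875 to 52314897 of chromosome 11, 31002 bp from the nearer gene end. A region inside Ikzf1, a lymphoid transcription factor, on chromosome 11 at 11725462 to 11726643 had a fold of 9.97 in the authors' deposited table. The list of CD8 and natural killer cell genes moved the same way, with 9 of 22 regions higher in naive cells (odds ratio 6.84, Fisher adjusted p = 0.000378), 3 each at Cd8b1 and Prf1. Ctla4 had 3 regions in each direction, Foxp3 1 higher in naive cells, and Ikzf2, Ifng and Tbx21 1 each higher in Th2 cells, whereas Cxcr3 and Il2ra had none. With genes as units the activation and tissue list passed in this direction as well as in the other (Fisher adjusted p = 0.0190 and 0.000172). The B cell list had 6 of 29 (Fisher adjusted p = 0.105).

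Naive versus Treg cells asked the same of regulatory cells. Treg genes were more accessible in Treg cells: 14 of the list's 20 genes and 53 of its 208 regions were higher than in naive cells (odds ratio 4.86, Fisher adjusted p = 1.66e-16). Ikzf2, the transcription factor Helios, had 10 regions, Il10 9, Ctla4 and Klrg1 6 each, Icos and Tigit 5 each, and Foxp3, the lineage-defining factor, 1. The Foxp3 region lay inside the gene on chromosome X at 7583946 to 7584606, with a fold of 8.47 in the authors' deposited table. Il2ra, which encodes the sort marker CD25, had 1. The Th2 list also passed, with 55 of 218 regions over 21 of 31 genes higher in Treg cells (odds ratio 4.80, Fisher adjusted p = 7.7e-17). Its members included Il1rl1 and Il10 with 9 regions each, Pparg with 6, Rbpj with 4, Areg with 3 and Ccr8, a chemokine receptor, with 2, whereas Il4, Il5 and Il13 had none and Rad50 had 1. Il10 is on both lists, so its regions count for each. The Th1 and Th17 list had 28 of 142 (odds ratio 3.47, Fisher adjusted p = 1.38e-06), mostly Rora with 10, Stat4 with 4, and Ccr6 and Il18rap with 3 each. Tbx21 had 1, and Ifng and Cxcr3 none. Atxn1 (12), Niban1 and Sh3rf1 (11 each), and Cdk6 and Ikzf2 (10 each) had most regions. In both directions together these were Bach2 (14), Wwox and Atxn1 (12 each), and Tgfbr3 and Niban1 (11 each). A pair of regions near Itgav, an integrin gene, on chromosome 2 at 83700441 to 83701407 and 83695210 to 83696043 had folds of -9.34 and -9.33, naive minus Treg, in the authors' deposited table.

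Naive cells were the higher population at 65 of 385 regions of the naive list (odds ratio 3.38, Fisher adjusted p = 9.26e-14), with Bach2 at 13 regions, Lef1 at 10, Tcf7 at 8, Foxp1 and Bcl2 at 7 and Ccr7 at 6. Outside the list, Tgfbr3 had 11, Cox10 8 and Ccr8 1. The region next to Tcf7 had the largest fold of naive versus Treg cells, 9.77 in the authors' deposited table. The CD8 and natural killer list had 5 of 22 regions higher in naive cells (odds ratio 4.82, Fisher adjusted p = 0.0231). That call ended without the tables of other effector cells (Fisher adjusted p = 0.149).

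Treg versus Th2 cells compared 2 of the 3 lung populations directly. Treg cells were higher at 34 of 208 regions of the Treg list, over 12 of 20 genes (odds ratio 5.75, Fisher adjusted p = 2.3e-13). Ikzf2 had 7 regions, Ctla4 and Icos 4 each, and Foxp3, Tnfrsf9 and Izumo1r 3 each, as did the sort marker gene Il2ra. The Th1 and Th17 list had 18 of 142 higher in Treg cells (odds ratio 4.24, Fisher adjusted p = 8.56e-06), 6 of them at Hopx and 4 at Rora. Ifng had 2, and Tbx21 1 in each direction, whereas Cxcr3 had none. Ccr7 and Lef1 had 1 each higher in Treg cells and Tcf7 1 higher in Th2 cells. Sh3rf1 and Nsmce2 (7 each) and Ankrd55 and Hopx (6 each) followed Ikzf2 among the genes with most regions.

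Th2 cells were higher at 19 of 218 regions of the Th2 list, which did not pass (odds ratio 1.33, Fisher adjusted p = 0.402), and its direction depended on the setting. With genes as units it passed (12 of 31 genes, odds ratio 3.31, Fisher adjusted p = 0.0121), whereas the odds ratio was 0.991 within 10 kb and 0.641 without the tables of other effector cells (Fisher adjusted p = 1 and 0.200). Il13 had 1 such region and Pparg 1, whereas Il4, Il5, Rad50, Gata3, Ccr8 and Il1rl1 had none. Bhlhe40 had 3. Hivep2, App and Runx1 (10 each), and Bach2 and Tbc1d1 (9 each) had most regions higher in Th2 cells, and Bach2 (11) and Rad51b (10) stood among the first in both directions together. The lipid list had 14 of 122 (Fisher adjusted p = 0.105), 5 of them at Cd36, a fatty acid transporter, and passed within 10 kb (Fisher adjusted p = 0.00932). Treg list regions were scarce, with 4 of 208 (odds ratio 0.271, Fisher adjusted p = 0.0112), which ended with genes as units (odds ratio 0.980, Fisher adjusted p = 1). That scarcity is not separate from the excess of the Treg list among regions higher in Treg cells. Myeloid genes had 8 of 50 higher in Th2 cells (odds ratio 2.65, Fisher adjusted p = 0.0502), which with genes as units passed (Fisher adjusted p = 0.00295). Without the tables of other effector cells neither the lipid nor the myeloid list passed (Fisher adjusted p = 0.284 and 0.240). Gata3 had 1 region higher in Treg cells, inside the gene on chromosome 2 at 9875945 to 9876210, with a fold of 6.17 in the authors' deposited table. On the unplaced sequence JH584304 at 58749 to 60116, Treg minus Th2 was -11.32 in the authors' deposited table, and whether reads map uniquely there was not examined. Regions near Spag16 on chromosome 1 at 69768467 to 69769483 and near Dusp1 on chromosome 17 at 26531484 to 26532277 were the furthest toward Treg cells, with folds of 9.36 and 9.15 in the authors' deposited table.

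**Figure D3:**
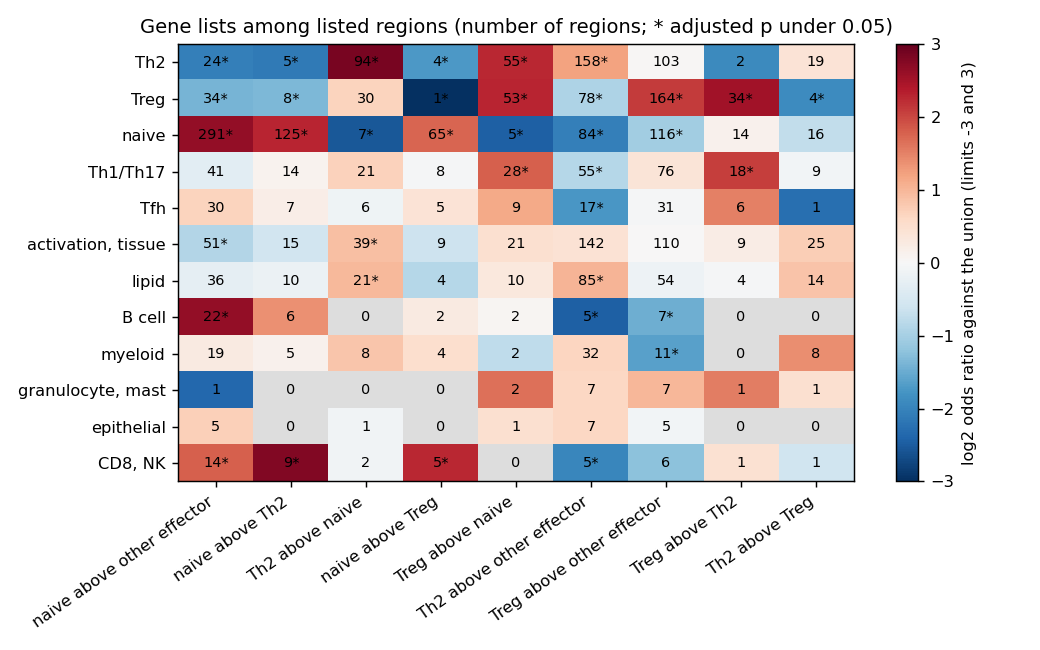
Gene lists (vertical axis) in the regions of each comparison and direction (horizontal axis). Colour gives the log2 odds ratio against all merged regions, limited to 3 on either side of 0, grey marks 0 regions, numbers are regions, and an asterisk marks an adjusted p under 0.05. The Th2 list stands out among regions higher in Th2 than in naive cells (94 regions) and the Treg list among regions higher in Treg than in Th2 cells (34 regions).

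Other effector cells were the lower population at all regions listed in their 3 comparisons. Against Th2 cells, Foxp1 had 28 regions, Runx1 27, Itpr1 and Zmiz1 26 and Atxn1 25. Against Treg cells, Foxp1 had 34, Nsmce2 30, Prkch 29, and Akap13 and Atxn1 28. Against naive cells, Foxp1 had 55, Bach2 50, Lef1 32, Satb1 30 and Tgfbr3 27. Each list carried genes of its higher population: 158 of 218 Th2 list regions in Th2 cells (odds ratio 2.32, Fisher adjusted p = 6.07e-08), 164 of 208 Treg list regions in Treg cells (odds ratio 4.27, Fisher adjusted p = 6e-20) and 291 of 385 naive list regions in naive cells (odds ratio 6.18, Fisher adjusted p = 9.54e-62), of which the last has no independent direction, since that list set the sign of its table. The lipid list, which shares Pparg with the Th2 list, had 85 of 122 higher in Th2 than in other effector cells (odds ratio 2.02, Fisher adjusted p = 0.00105). Myeloid genes had 32 of 50 regions over 8 of 9 genes higher in Th2 (odds ratio 1.56, Fisher adjusted p = 0.295) and 11 of 50 higher in Treg than in other effector cells (odds ratio 0.321, Fisher adjusted p = 0.00209). Of these, the call in Treg cells ended within 10 kb (Fisher adjusted p = 0.0561) and with genes as units (Fisher adjusted p = 1). With genes as units, the calls of the Th2 and lipid lists in Th2 over other effector cells ended (Fisher adjusted p = 0.470 and 0.809). B cell genes had 22 of 29 regions higher in naive than in other effector cells (odds ratio 6.19, Fisher adjusted p = 2.49e-05), 12 of them at Ebf1, and CD8 and natural killer genes had 14 of 22 (odds ratio 3.45, Fisher adjusted p = 0.0175). Gata3 had 5 regions higher in Th2 and 9 higher in Treg than in other effector cells. Il13 had 6 and 1, Il1rl1 16 and 15, Pparg 11 and 9, Foxp3 0 and 5, Ifng 2 and 5, Tbx21 2 and 1, and Cxcr3 0 and 0. Il4 had 1 and 0, Il5 and Rad50 4 and 1 each, Ccr8 0 and 2, Il2ra 7 and 14, Ctla4 4 and 17, Ikzf2 5 and 26, Ccr7 0 and 4, Tcf7 3 and 3, and Lef1 0 and 11. Higher in naive than in other effector cells were 14 regions of Ccr7, 12 of Tcf7, 5 of Ikzf2, 3 each of Ctla4, Il2ra and Ifng, and 1 each of Gata3, Ccr8 and Foxp3, and none of Il4, Il5, Il13, Rad50, Il1rl1, Pparg, Tbx21 or Cxcr3.

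The largest folds of these 3 lists lay outside genes. On chromosome 1, a segment nearest to Col19a1 whose sequence is known to resemble mitochondrial DNA had folds of 15.60, 14.41 and 12.98 over other effector cells in naive cells, at 24611921 to 24613049, 24614352 to 24614734 and 24611464 to 24611715, in the authors' deposited table. The second of these had folds of -12.98 for other effector minus Th2 and -12.81 for other effector minus Treg cells in the authors' deposited table. On chromosome 2 at 98667058 to 98667380, 1035546 bp from the nearest gene end, the folds were -15.08 and -14.06 in the authors' deposited table. Its neighbour at 98666179 to 98666722 had -13.45 and -12.92 in the authors' deposited table. Whether reads map uniquely at these positions of chromosomes 1 and 2 was not examined, so their folds need not measure accessibility.

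Regions within 1 kb of a gene end made up 29.6% (95% exact interval 29.0% to 30.1%) of those higher in Th2 and 30.4% (29.8% to 31.0%) of those higher in Treg than in other effector cells. Of those higher in naive than in other effector cells the share was 10.4% (9.97% to 10.9%). It was 10.6% among regions higher in Th2 than in naive cells and 5.40% among those higher in naive cells (odds ratio 0.481, Fisher adjusted p = 1.78e-21). For Treg and naive cells the shares were 8.08% and 5.79% (Fisher adjusted p = 0.000416).

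Th2 and Treg cells shared part of their difference from naive cells. Of the regions higher in Th2 than in naive cells, 1379 (27.2%) were also higher in Treg than in naive cells, where independent lists would share 337. Naive cells were higher than both at 1422 regions, against 279 for independent lists. Both comparisons use the same naive libraries, and the part of each excess that comes from them cannot be simulated without replicates. Of the 1379 regions, 1356 (98.3%) were also lower in other effector cells than in both, much as 98.3% of all regions higher in Th2 than in naive cells were higher in Th2 than in other effector cells, and 99.2% for Treg cells. Regions listed in all 3 comparisons of a population and in none of the others numbered 1418 for naive, 1257 for Th2 and 635 for Treg cells, all higher in that population, and 1845 for other effector cells, all lower. Independent lists would give 92.9, 164, 77.1 and 2813. The 3 comparisons of a population share its libraries, and every merged region is in at least 1 list, so independence is no fair reference. Neither the higher counts of naive, Th2 and Treg cells nor the lower count of other effector cells can be weighed against it. Naive-distinguishing regions were most frequent at Tgfbr3 (10), Lef1 (8), Slc4a4 (7), Adamts20 (6) and Bach2 (5). Those of Th2 cells led at Itpr1 and Creb5 (6 each), then Prr5l, Etv6 and Tnfaip8 (5 each), and those of Treg cells at Sh3rf1 and Nsmce2 (5 each), then H2az1, Icos and Stk39 (4 each). Trio, Fam107b, Rapgef2 and Crtc3 (5 each) and Myo3a (4) led for other effector cells.

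Windows of 100 kb were compared with the number of listed regions that their merged regions would give, a test added after the data were examined. The window of Lef1 on chromosome 3 at 131100001 to 131200000 had 15 listed of 24 merged regions for naive versus Th2 cells, where its merged regions would give 4.53 (exact hypergeometric tail, adjusted p = 0.00924), and 21 for naive versus other effector cells, against 8.09 (exact hypergeometric tail, adjusted p = 0.000223). Satb1 on chromosome 17 had 14 of 19 for naive versus Th2 cells and Tgfbr3 on chromosome 5 had 12 of 14 (exact hypergeometric tail, adjusted p = 0.00126 for each). Ccr7 on chromosome 11 had 18 of 20 for naive versus other effector cells (exact hypergeometric tail, adjusted p = 0.000542). Of 11857 windows, 57 passed this test for naive versus other effector, 9 for naive versus Th2 and 3 for naive versus Treg cells, and 0 in each of the other comparisons. The planned Poisson test, which takes the same mean for all windows and so passes windows dense in merged regions, gave 415, 100 and 85, and 333, 460 and 44 for other effector versus Th2, other effector versus Treg and Treg versus Th2 cells. The window of Nsmce2 on chromosome 15 passed it for Treg versus Th2 cells with 7 of 25, against 2.52 given its merged regions (exact hypergeometric tail, adjusted p = 0.769). Across chromosomes, 39 of 126 tests passed. On the X chromosome the odds ratio was 1.28 for naive versus other effector, 0.751 for naive versus Th2 and 0.650 for Treg versus Th2 cells (Fisher adjusted p = 0.000836, 0.00301 and 0.00124). Apart from the Y chromosome, the highest odds ratio of any chromosome was 1.31. The Y chromosome held 7 regions of other effector versus Treg cells (Fisher adjusted p = 0.0191).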

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

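Among the tests below, the 2 on housekeeping genes lower in other effector cells in at least 1 comparison were set before their result was seen, and the others after. Of the regions listed against naive cells, 51.2% were higher in Th2 and 53.6% in Treg cells, and 0% of 17700 were higher in other effector cells as its sign was read. Fisher's exact test of this difference restates the one-sided list that prompted it, so it decides nothing. Among regions higher than naive in only 1 of Th2 and Treg cells, Treg list regions had an odds ratio of 0.171 for Th2 over Treg (10 against 33 regions, Fisher adjusted p = 8.77e-07) and Th1 and Th17 list regions 0.378 (14 against 21, Fisher adjusted p = 0.0273). A signal also lay outside the chromosomes: on the unplaced sequence JH584304, naive minus Th2 reached -11.49 in the authors' deposited table. Unique mapping of reads there was not examined, so this fold need not measure accessibility.

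The one-sided lists of other effector cells were weighed first. Lower accessibility confined to subset-restricted genes was argued against, for the lists against Th2 and Treg cells, by housekeeping genes (23 and 20 of 30). In at least 1 comparison 83.3% of 30 had a gene-end region lower in other effector cells, with a lower limit of 65.3%, above the highest upper limit in another population, 17.2%. That contrast follows list length, since 49.7% of all protein-coding genes were lower in other effector cells and 1.86% to 3.14% in the other populations. Against naive cells the share was 13.3% (interval 3.76% to 30.7%), so this explanation stays open there. A different number of libraries or a stricter test stays open, since list length (17700 regions in the shortest, against 9916 in the longest without other effector cells) does not bear on direction. Low signal across the whole genome in the other effector libraries had the share it needs (83.3%, against 49.7% of all protein-coding genes). It may account for the list against Treg cells, where 10 of 15 genes used by all T cells also had a lower gene-end region. Against Th2 cells only 3 of those 15 did, beside 23 of 30 housekeeping genes, so low signal at every gene is less clear there. Cd3e and Cd4 were themselves lower in Th2 than in naive cells, so that count does not decide it. Against naive cells low signal remains open, because only 13.3% of housekeeping genes (interval 3.76% to 30.7%) were lower in other effector cells there. The biological difference between populations and the day given as D10 in some labels stay untested. So does removal of regions higher in other effector cells before deposit. Such removal alone would make the lists one-sided, but would not set which lower regions they hold.

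No listed fold was small, the lowest lying between 3.41 and 3.95. A fixed fold limit that set the lowest fold of every list was argued against by the range of these minima, 0.54 on the log2 scale. A limit at or below 3.41 beside another threshold could leave the same minima and stays open. A common near-zero level in the lower population had the value it needs: where 1 population was above 2 others at identical coordinates, the lower 2 differed by a median of 0.18, so many folds may measure the higher population against a floor. This does not hold for every region, since the 95th percentile of that difference was 0.51 to 2.31 and only 41.5% to 87.9% of regions lay within 0.02 of their median difference. No biological explanation was tested.

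Gata3, the factor that defines Th2 cells, had no region higher in Th2 than in Treg cells and 1 higher in Treg cells. Th2 and Treg labels exchanged were argued against, with 0 regions of Foxp3, Il4, Il13 and Rad50 in the exchanged direction and 4 in the labelled one, and with Il13 at 5 regions in Th2 and 0 in Treg cells against naive cells. It may be that Gata3 regions open in several populations are left out by lists of large folds, since 5 were higher in Th2 and 9 in Treg than in other effector cells. Levels of Gata3 accessibility are not given in the sources used here, and no biological explanation was tested.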

How the results depend on the processing

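No paired analysis was possible because the tables hold no replicates, and for the same reason no replicate was left out. With no FDR in the tables, the stricter threshold was the part of each list with the larger folds, which by construction gave 8850, 4958, 3258, 14087, 12382 and 2650 regions (naive versus other effector, Th2 and Treg, other effector versus Th2 and Treg, Treg versus Th2). It put 44.0% of naive versus Th2, 39.5% of naive versus Treg and 34.5% of Treg versus Th2 regions in the first population, and gave 534 naive, 494 other effector, 652 Th2 and 347 Treg distinguishing regions. It moved the sharing of naive versus other effector with other effector versus Th2 to 0.219 of expected, and that of naive versus Th2 with other effector versus Th2 from 0.947 to 1.02, the other side of 1. Shares near gene ends rose to 17.2%, 13.7%, 12.2%, 37.2%, 38.5% and 17.0% with 2.5 kb and to 12.1%, 9.47%, 8.10%, 31.4%, 32.3% and 12.3% with any overlap, as wider windows must. Windows of 50 kb gave 275, 29, 34, 152, 240 and 14 clusters in the same order, and windows of 500 kb 187 for naive versus Th2, 508 for other effector versus Th2 and 86 for Treg versus Th2; the cause was not tested. With genes as units, 1 gene list lay below the rest and the odds ratios turned for the Treg list (2.49) and the activation list (1.97) in naive versus other effector and for the Treg list in other effector versus Th2 (4.12), none of which passed. By single direction, genes as units kept 17 of 37 calls, lost 20, of which 6 turned, and added 13, among them the activation (Fisher adjusted p = 0.0190) and Tfh lists (0.0193) in naive over Th2 and the naive list in Treg over Th2 cells (0.000517). That setting favours lists with many regions per gene, so calls that it adds or turns settle no direction. Regions within 10 kb lost 4 and added 2, any distance lost 0 and added 6, and the 3 tables without other effector cells lost 3 of 19 and added 4. The next 3 alternatives were chosen after seeing the data. The 3 tables without other effector cells gave 2799 naive distinguishing regions, 3 gene lists above and 3 below the rest, with fewer tests, and an odds ratio of 0.998 for the naive list in naive versus Treg. Single directions gave 19 lists below. Windows tested given their own merged regions gave 57, 9, 3, 0, 0 and 0 clusters in the order above, by construction without those that are only dense in merged regions. Of the alternatives planned, 122 values kept direction and side or stayed within their limits and 11 gene list odds ratios kept direction but no longer passed. A further 36 moved past their limits and 4 changed direction or side. Of those added, 46 kept, 6 no longer passed, 10 moved and 1 changed direction or side. Depth limits all of this to an unknown extent.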

Other observations

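Of 15 genes used by all T cells, a list written after the tables were first seen and before its counts were, 11 had a gene-end region higher in naive than in other effector cells, 10 higher in Treg and 3 (Cd2, Cd6 and Ptprc) higher in Th2 cells. Of 30 housekeeping genes the counts were 4, 20 and 23, and the difference between both sets was not tested. Cd3e and Cd4 had a gene-end region higher in naive than in Th2 cells, and Cd4 also one higher in Treg than in Th2 cells. Such regions lie within 1 kb of an end of the gene but may be assigned to a neighbouring gene.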
